A study of Homo sapiens with 2 samples.

How the data were processed

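Poly(A) RNA of OVCAR5 cells carrying a hairpin RNA against DOT1L was sequenced in 2 libraries, replicates 1 and 2 of 1 group. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, mRNA was purified on Dynabeads, and libraries were made with the NEBNext Ultra II RNA kit. The submitters' processing notes name STAR 2.5.2, HTSeq, edgeR and GRCh38. Aligner settings, the gene annotation, the strand setting and the treatment of reads shared between genes are not given in the sources used here, so a gene and an overlapping antisense gene may share reads. Each deposited table holds 1 whole-number read count per gene symbol, not normalized, for 56655 symbols. No row of unassigned reads is present, 31131 symbols had a read in either library and 25524 had none.

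Counts summed to 19427483 in replicate 1 and 22599556 in replicate 2. A level of 1 CPM is 19.4 and 22.6 reads, and 0 reads allow up to 0.154 and 0.133 CPM, the level of 3 reads. Levels are CPM over all assigned reads. Ratios between libraries use the effective sizes of edgeR 4.0.16 (trimmed mean of M values, TMM; factors 1.01 and 0.993) with 0.5 reads added to each count. Positions, gene types and exon lengths came from GENCODE 29 on GRCh38, matched by symbol. It holds 97.7% of the symbols, with 99.5% of the counts, and may not be the release the authors counted on. Of the fixed list members 7 were found under an older symbol.

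The 21 lists and the tests of the report, and the rule for named genes, were fixed before the data were examined; the gene groups and most tests of the closing observations were chosen after. The rule takes DOT1L, and from each of 21 lists up to 4 highest and 3 lowest detected members, members under 1 CPM in both libraries, and textbook transcription factor and receptor genes. It also takes the 10 most abundant nuclear protein-coding genes, and the 5 largest ratios in each direction among genes with an adjusted p under 0.05 and a mean of at least 50 reads. Genes that passed 1 CPM in 1 library only, the markers singled out because they alone differed, and MLLT1, MUC16 and MTAP were named after their values were seen. Detection means at least 1 CPM in both libraries. Some genes that the rule takes are not reported here, though counts and medians of lists include them.

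With 1 group there was no contrast between conditions, and edgeR's quasi-likelihood test had no second group. Replicate 2 was instead set against replicate 1 by an exact two-sided binomial test per gene, with at least 10 reads in all, Benjamini-Hochberg adjustment and Clopper-Pearson intervals. It compares those libraries, not conditions. A chi-square test of homogeneity asked whether the tables could be one library. The biological coefficient of variation is the square root of edgeR's common dispersion, with 1 residual degree of freedom per gene. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Counts were simulated for 18962 genes with counting error only and no variation between cultures. On these the binomial test recovered 52% of 50 genes changed by 1.2-fold, 88% at 1.5-fold, 92% at 2-fold and 100% at 4-fold. It called 5 of 18762 unchanged genes, a rate that need not hold for cultures that vary. A simulated coefficient of variation of 0.1 came back as 0.0996 from edgeR and 0.136 from DESeq2.

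Alternatives were other scalings (DESeq2 1.42.0 size factors, total counts), detection levels of 0.5 and 2 CPM or 10 reads, pseudocounts of 0.5 and 0.1, reads per kb of exon, other denominators and each library alone. Tests ran in R 4.3.3 and Python 3.11.15 with scipy 1.17.1.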

Results

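The transcriptome of OVCAR5 cells was measured after transduction with a short hairpin RNA against DOT1L, the histone methyltransferase that places methyl groups on lysine 79 of histone H3. OVCAR5 is an established ovarian cancer cell line, labelled high grade serous with ascites as its source. Poly(A) RNA from 2 transduced cultures, described by the submitters as biological duplicates, was sequenced, and both libraries belong to 1 group, shDOT1L. Replicate 1 held 19427483 reads assigned to genes and replicate 2 held 22599556. Libraries of control cells, and the chromatin immunoprecipitation dataset for H3K79 methylation that the series also describes, were not analysed here. The values therefore describe which genes the transduced cells expressed and how far the 2 cultures differed, and no effect of the hairpin was measured. Levels are reads of a gene scaled to the total assigned to genes (CPM), given as mean ± SD over the 2 libraries (n = 2), and a gene counts as detected at 1 CPM or more in both. By that measure 13877 genes were detected, of which 12129 were protein-coding genes of the nuclear genome. A gene with 0 reads allows a level of up to 0.154 CPM in replicate 1 and 0.133 CPM in replicate 2, the level of 3 reads. All intervals and floors cover counting error only, and an SD over 2 libraries can come out smaller than counting error.

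The most abundant nuclear messages came from cytoskeleton, glycolysis, chaperone, chromatin and translation genes. ACTB, which encodes beta-actin, led with 6107 ± 21.7 CPM, and PKM, the pyruvate kinase gene, followed with 4942 ± 312 CPM. HSP90AA1, a heat shock chaperone gene, had 3907 ± 565 CPM and HMGA1, the gene of an architectural chromatin protein, 3810 ± 824 CPM. RPL8 had 3752 ± 17.7 CPM, KRT8 3715 ± 225 CPM, ENO1 3464 ± 234 CPM, ACTG1 3123 ± 289 CPM, RPS3 2872 ± 138 CPM and EEF1A1 2868 ± 325 CPM. The actin, keratin, ribosomal protein and elongation factor genes have near-identical copies elsewhere in the genome, so their levels are uncertain. The 10 most abundant genes of any kind, those of the mitochondrial genome included, took 6.95% ± 0.063 of assigned reads. Genes of the mitochondrial genome took 7.44% ± 0.044, and ribosomal protein genes 6.45% ± 0.322. Within single libraries, mitochondrial reads made up 7.47% in replicate 1 (95% Wilson interval 7.46 to 7.48) and 7.41% in replicate 2 (7.40 to 7.42).

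DOT1L itself, the target of the hairpin, was expressed in both libraries. The gene (ENSG00000104885.17) lies on chromosome 19 from 2164149 to 2232578 on the plus strand of GRCh38, and 88.5% of its 11272 annotated exon bases are free of exons of other genes. It had 819 reads in replicate 1, or 42.2 CPM with an exact 95% Poisson interval of 39.3 to 45.1, and 1148 reads in replicate 2, or 50.8 CPM with an interval of 47.9 to 53.8. The mean of 46.5 ± 6.11 CPM placed it at the 61.0th percentile of detected protein-coding genes. Per kb of exon it stood at the 40.6th percentile, since its transcript is long. Replicate 2 exceeded replicate 1 by 1.22-fold after scaling, a log2 ratio of 0.29 (95% interval 0.16 to 0.42, adjusted p = 7.99e-05, exact two-sided binomial test with Benjamini-Hochberg adjustment). That test compares the reads of these 2 libraries, not conditions. Whether and how far the hairpin lowered DOT1L could not be measured without control libraries.

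Most genes of the DOT1L complexes were expressed along with it. Of 21 list members, 18 were detected. NPM1, which encodes nucleophosmin, was the highest at 1076 ± 19.5 CPM, followed by KMT2A, the histone H3 lysine 4 methyltransferase of the leukaemia fusions, at 152 ± 12.3 CPM. MLLT6, the gene of the DOT1L cofactor AF17, had 138.5 ± 17.0 CPM and SKP1, a ubiquitin ligase component, 136 ± 5.48 CPM. The lowest detected members were MLLT10, the gene of the cofactor AF10, at 25.7 ± 1.03 CPM, the elongation factor gene ELL2 at 16.1 ± 1.11 CPM, and MLLT3, which encodes AF9, at 6.93 ± 0.168 CPM. MLLT1, which encodes ENL, a homologue of AF9, had 121 ± 2.26 CPM; it was added to the named genes after its value was seen. ELL3, AFF2 and AFF3 stayed under 1 CPM in both libraries.

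**Figure D1:**
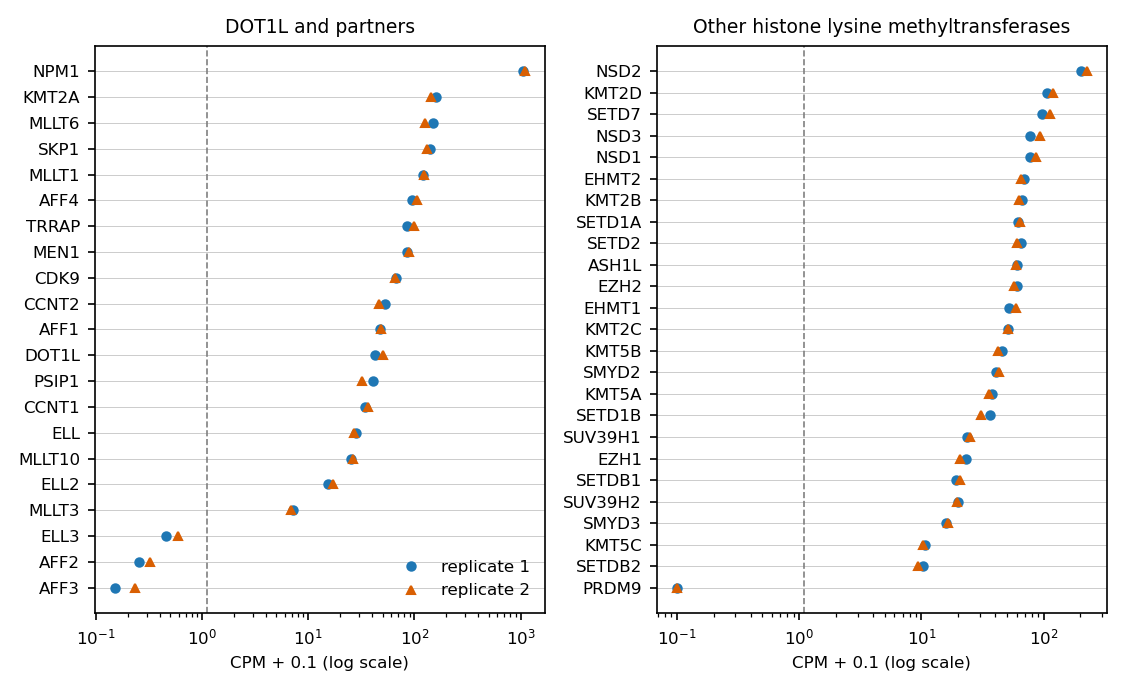
Levels of DOT1L and its partners (left) and of the other histone lysine methyltransferases (right), as CPM plus 0.1 on a log axis, with 1 point per library; the dashed line marks the detection level of 1 CPM. DOT1L had 42.2 and 50.8 CPM, and ELL3, AFF2, AFF3 and PRDM9 lay below the line.

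Of 25 other lysine methyltransferase genes 24 were detected, and the median of all members was 50.9 CPM. NSD2, a histone H3 lysine 36 methyltransferase gene, led with 214 ± 14.5 CPM. KMT2D, a lysine 4 methyltransferase gene active at enhancers, had 113 ± 8.07 CPM, SETD7 105 ± 12.02 CPM and NSD3 84.6 ± 11.5 CPM. SMYD3 had 16.1 ± 0.371 CPM, KMT5C 10.3 ± 0.229 CPM and SETDB2 9.74 ± 0.636 CPM. PRDM9, the methyltransferase gene of meiosis, had 0 reads.

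The posterior HOXA genes and their homeobox cofactors, known as DOT1L-dependent genes in leukaemia with KMT2A fusions, were expressed at low levels. Of 11 members 9 were detected, and the median of all 11 was 7.30 CPM. The homeobox genes MEIS2 at 41.0 ± 1.11 CPM and MEIS1 at 29.9 ± 0.600 CPM were the highest, ahead of HOXA5 at 19.3 ± 1.89 CPM and HOXA11 at 11.4 ± 0.539 CPM. HOXA6 had 3.46 ± 0.741 CPM, HOXA13 2.39 ± 0.317 CPM and HOXA9 1.86 ± 0.306 CPM. HOXA7 stayed under 1 CPM in both libraries, and HOXA10 passed 1 CPM in replicate 2 only.

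Markers of gastrointestinal epithelium and of Müllerian epithelium were both present, and each list held genes at high level beside genes with almost no reads. Among the 18 Müllerian and serous ovarian markers 11 were detected. WFDC2, which encodes the secreted protein HE4, had 321 ± 90.4 CPM, MECOM 26.0 ± 0.0819 CPM and the protease gene KLK6 24.4 ± 3.44 CPM. The transcription factor gene GATA4, a list member that is not specific to this lineage, had 43.4 ± 3.08 CPM. PAX8, the transcription factor gene used to diagnose Müllerian tumours, had 19.2 ± 1.67 CPM. FOLR1 at 4.92 ± 0.391 CPM, OVGP1 at 2.71 ± 0.760 CPM and LYPD1 at 1.86 ± 0.879 CPM were the lowest detected. MUC16, which carries the antigen CA125 and was named after its value was seen, had 7.79 ± 2.06 CPM. The transcription factor genes WT1 and EMX2 had 1 read each over both libraries and SOX17 had 0. The steroid receptor genes ESR1 and PGR, and CLDN16 and KLK7, also stayed under 1 CPM in both.

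Among the 22 gastrointestinal markers 15 were detected. MUC5AC, a gel-forming mucin gene of the gastric surface, had 599.5 ± 296 CPM, AGR2 322 ± 6.61 CPM, the adhesion molecule gene CEACAM6 265 ± 52.4 CPM and KRT20, a keratin gene of intestinal epithelium, 115 ± 5.02 CPM. The gut transcription factor genes GATA6, CDX2 and HNF4A had 10.6 ± 1.77, 10.3 ± 2.33 and 8.63 ± 0.627 CPM. TFF1, TFF2 and VIL1 were the lowest detected, at 2.73 ± 1.90, 2.61 ± 0.932 and 1.48 ± 0.460 CPM. CDX1 had 0 reads, and CDH17, LGALS4, GPA33, TFF3 and PHGR1 stayed under 1 CPM in both libraries. The median of log2(CPM + 1) over all members was 2.63 for the gastrointestinal list and 2.23 for the Müllerian list. That difference of 0.40 came from replicate 2, where it was 0.69, against 0.02 in replicate 1. Per kb of exon the difference was 1.25, and at a detection level of 2 CPM the gastrointestinal list had the lower share detected, by -5.56 percentage points against 7.07 at 1 CPM.

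**Figure D2:**
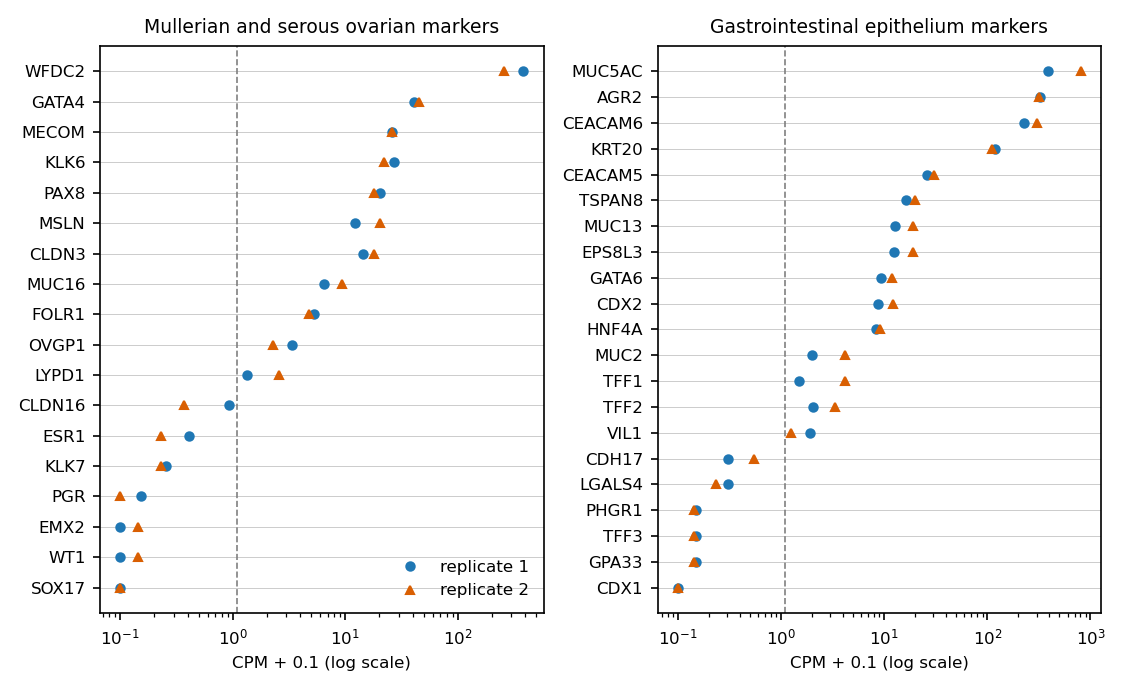
Levels of the Müllerian and serous ovarian markers (left) and the gastrointestinal epithelium markers (right), as CPM plus 0.1 on a log axis, with 1 point per library; the dashed line marks 1 CPM. Of the markers shown, 7 on the left and 6 on the right lay below the line in both libraries, and MUC5AC had 390.2 CPM in replicate 1 and 809 CPM in replicate 2.

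Epithelial genes were highly expressed, beside a partial set of mesenchymal genes. All 18 epithelial genes were detected, at a median of 164 CPM. The simple-epithelium keratin genes KRT8, KRT18, KRT19 and KRT7 led with 3715 ± 225, 1872 ± 341, 1160 ± 49.5 and 1046 ± 179.7 CPM. The lowest were the cadherin gene CDH3 at 16.6 ± 2.61 CPM, the tight junction gene OCLN at 11.5 ± 2.71 CPM and OVOL1, an epithelial transcription factor gene, at 8.27 ± 2.52 CPM. Of the 18 mesenchymal genes and regulators of the epithelial-mesenchymal transition, 12 were detected. TGFBI, an extracellular matrix gene induced by TGF-beta, had 1342 ± 206 CPM, CTGF 168 ± 93.9 CPM, the intermediate filament gene VIM 112 ± 19.6 CPM and the fibronectin gene FN1 72.5 ± 30.1 CPM. Among the transcription factor genes that drive the transition, SNAI2 had 24.5 ± 4.43 CPM, ZEB1 9.76 ± 0.843 CPM and SNAI1 5.14 ± 0.0103 CPM, while ZEB2, TWIST1 and TWIST2 stayed under 1 CPM in both. The contractile genes TAGLN and ACTA2 had 3.32 ± 0.321 and 2.48 ± 0.50 CPM. CDH2, the N-cadherin gene, had 3 reads in replicate 1 and 0 in replicate 2, and MMP2 and CDH11 were likewise under 1 CPM.

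Proliferation genes were highly expressed. Of 23 cell cycle genes 22 were detected, and the median of all 23 was 109 CPM. The highest were the topoisomerase gene TOP2A at 651 ± 18.4 CPM and the cyclin D1 gene CCND1 at 535 ± 56.3 CPM. The proliferation marker MKI67 followed at 433 ± 25.6 CPM and the replication helicase gene MCM5 at 271 ± 4.10 CPM. RB1, CCNE1 and CCNE2 were lowest, at 41.3 ± 3.80, 13.1 ± 3.08 and 4.59 ± 1.46 CPM. CCND2, the cyclin D2 gene, had 2 reads in each library. Of 17 cell cycle inhibitor and damage response genes 15 were detected, and the median of all 17 was 16.8 CPM. BAX had 79.1 ± 6.09 CPM, the stress gene GADD45A 45.8 ± 15.2 CPM, and the inhibitor genes CDKN1B and CDKN1A 42.4 ± 2.75 and 37.8 ± 3.37 CPM. SESN1, CDKN2D and BBC3 were lowest, at 3.90 ± 0.752, 3.45 ± 0.507 and 2.73 ± 0.146 CPM. CDKN2A and CDKN2B, the inhibitor genes of chromosome 9 at 21967753 to 21995301 and 22002903 to 22009363, had 0 reads in both libraries, as did the neighbouring MTAP.

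Apoptosis and repair genes were nearly all expressed. Of 18 apoptosis regulators 17 were detected, with the inhibitor of apoptosis gene BIRC3 at 565 ± 57.7 CPM, the cytochrome c gene CYCS at 456 ± 40.6 CPM, the anti-apoptotic gene BCL2L1 at 397 ± 15.03 CPM and the survivin gene BIRC5 at 279.9 ± 11.1 CPM. BAK1 and APAF1 were the lowest detected, at 16.8 ± 1.74 and 13.6 ± 2.49 CPM. BCL2 had 18 and 21 reads, or 0.928 ± 0.00191 CPM, under the limit by less than counting error. All 22 DNA repair genes were detected, at a median of 40.3 CPM. PARP1 had 159.8 ± 13.3 CPM, the kinase gene ATM 86.6 ± 1.59 CPM, the mismatch repair gene MSH6 74.4 ± 11.5 CPM and BRCA1 74.0 ± 3.49 CPM. XPA, PMS2 and BRIP1 were the lowest at 19.1 ± 3.86, 17.0 ± 1.52 and 9.29 ± 0.184 CPM.

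Most genes of canonical Wnt signalling were expressed, with 26 of 28 members detected. The coreceptor gene LRP5 had 419 ± 19.8 CPM, the beta-catenin gene CTNNB1 307 ± 46.5 CPM, MYC 205 ± 17.9 CPM and DVL1 122 ± 0.180 CPM. The receptor genes LGR4 and FZD1 had 100.2 ± 35.9 and 51.7 ± 21.9 CPM. NKD1, LEF1 and AXIN2 were the lowest detected members, with 2.28 ± 0.531, 1.81 ± 0.446 and 1.69 ± 0.358 CPM. These genes are induced by the pathway, but so is MYC. The stem cell receptor gene LGR5 had 0 and 2 reads, and SP5 reached 1 CPM in replicate 1 only.

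Of 20 genes used as ovarian cancer stem cell markers 14 were detected. CD44, the hyaluronan receptor gene, had 492 ± 57.6 CPM, ALDH1A3 423 ± 17.9 CPM, and the transcription factor genes SOX9 and KLF4 104 ± 12.9 and 102 ± 10.7 CPM. POU5F1, ALDH1A1 and SOX2 were the lowest detected, at 2.90 ± 0.411, 1.73 ± 0.186 and 1.64 ± 0.309 CPM; POU5F1 shares sequence with its pseudogenes. ALDH1A2, LIN28A, ABCB1, NANOG and LIN28B stayed under 1 CPM in both libraries, and KIT reached it in replicate 2 only.

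Glycolysis genes were among the most abundant of all. Of 22 members 21 were detected, and the median of all 22 was 249 CPM. PKM had 4942 ± 312, ENO1 3464 ± 234, the aldolase gene ALDOA 2667 ± 278 and GAPDH 2461 ± 319 CPM. PDK1, ENO2 and SLC2A3 were lowest, at 21.2 ± 0.299, 19.1 ± 2.10 and 4.47 ± 0.129 CPM. LDHB, the gene of a lactate dehydrogenase subunit at 21635342 to 21757857 on chromosome 12, had 0 reads in both libraries. All 23 nuclear-encoded oxidative phosphorylation genes were detected, at a median of 162 CPM. ATP5B, an ATP synthase gene, had 678 ± 166 CPM, CYC1 504.5 ± 109 CPM, COX4I1 393 ± 8.34 CPM and NDUFV1 371 ± 26.3 CPM, against 47.8 ± 7.15 CPM for ATP5O, 22.7 ± 4.81 CPM for NDUFA9 and 17.2 ± 0.686 CPM for NDUFB8.

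Interferon-stimulated genes were expressed at intermediate levels, with 23 of 24 detected and a median of 30.7 CPM over all 24. IFI27, an interferon-inducible gene, had 154 ± 51.6 CPM, the tetherin gene BST2 117 ± 14.4 CPM and the ubiquitin-like modifier gene ISG15 113 ± 10.9 CPM. TLR3, IRF9 and IFI44L were the lowest detected, at 4.79 ± 1.103, 2.78 ± 0.869 and 1.97 ± 0.412 CPM, and CXCL10 reached 1 CPM in replicate 2 only.

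Markers of other cell types were mostly under the detection level. Of 16 leukocyte markers 3 were detected: LYZ, the lysozyme gene, at 23.5 ± 12.4 CPM, CD14 at 6.93 ± 0.1003 CPM and ITGAM at 1.02 ± 0.00831 CPM. PTPRC, the pan-leukocyte gene CD45, had 0 reads, and CSF1R, CD8A, CD79A, CD4, CD68, CD3E, NKG7, CD3D, MS4A1, CD163 and FCGR3A were among those under 1 CPM in both. Among 10 fibroblast markers COL1A1 alone was detected, at 24.5 ± 1.84 CPM, while PDGFRB, FAP, POSTN, PDGFRA, THY1, COL3A1, COL1A2, DCN and LUM were under 1 CPM. Among 11 endothelial and erythroid markers PECAM1 alone was detected, at 11.7 ± 2.46 CPM, and CDH5, VWF, HBA2, TEK, ALAS2, HBA1, KDR, EMCN and HBB were among those that were not. Of 8 mesothelial markers 3 were detected, with the calretinin gene CALB2 at 204 ± 40.8 CPM, UPK3B at 5.29 ± 0.161 CPM and LRRN4 at 2.72 ± 1.03 CPM. DES, KRT5, BNC1, ITLN1 and PDPN stayed under 1 CPM. All 14 housekeeping genes were detected, from ACTB, EEF1A1, RPLP0 at 1859 ± 161 CPM and B2M at 1509 ± 109 CPM down to GUSB at 62.2 ± 0.445 CPM, HPRT1 at 59.7 ± 6.51 CPM and TBP at 19.3 ± 0.476 CPM.

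Among genes with an adjusted p under 0.05 and a mean of at least 50 reads, CXCL5 and CXCL3 had the largest ratios between the 2 cultures. These genes of chemokines that attract neutrophils were 9.99-fold and 6.00-fold higher in replicate 2 than in replicate 1. Their log2 ratios were 3.32 (95% interval 3.12 to 3.54) and 2.58 (2.48 to 2.69); CXCL3 has close homologues with which it can share reads. The immediate early transcription factor gene EGR2 had a log2 ratio of 2.21 (1.47 to 3.12), PTGS2, which encodes the prostaglandin synthase COX-2, 2.16 (1.91 to 2.42), and FCGBP, the gene of a protein of intestinal mucus, 1.90 (1.71 to 2.09). In the other direction ULBP1, the gene of a ligand of the natural killer receptor NKG2D, had a log2 ratio of -1.98 (-2.54 to -1.48). The pseudogenes TPSP2 and NPIPP1 followed with -1.73 and -1.43, where reads can come from their parent families, then CCDC152 with -1.43 and the long noncoding gene AL390728.6 with -1.42. Adjusted p-values of these 10 genes were 8.24e-06 or lower by the exact two-sided binomial test with Benjamini-Hochberg adjustment.

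Across all genes the 2 libraries were close but not the same library. Pearson's r of log2(CPM + 1) was 0.990 and Spearman's rho 0.990 over the 13877 detected genes, which are not independent replicates. The chi-square statistic of homogeneity was 17.5 times its 18930 degrees of freedom, so the libraries differed by more than sampling noise. The biological coefficient of variation, estimated with edgeR from 15682 genes, was 0.137. Among the 7180 genes with at least 1000 reads, 95.04% had a log2 ratio within 0.5 of 0 and 99.5% within 1. Of 18931 genes tested, 5754 differed at an adjusted p under 0.05 by the exact binomial test, 3111 higher and 2643 lower in replicate 2; 180 of the higher and 267 of the lower genes differed by at least 2-fold. With DESeq2 size factors the split was 3736 higher and 2196 lower, and with total counts 2788 higher and 2888 lower. This test reads only counting error, so variation between cultures adds to its calls.

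**Figure D3:**
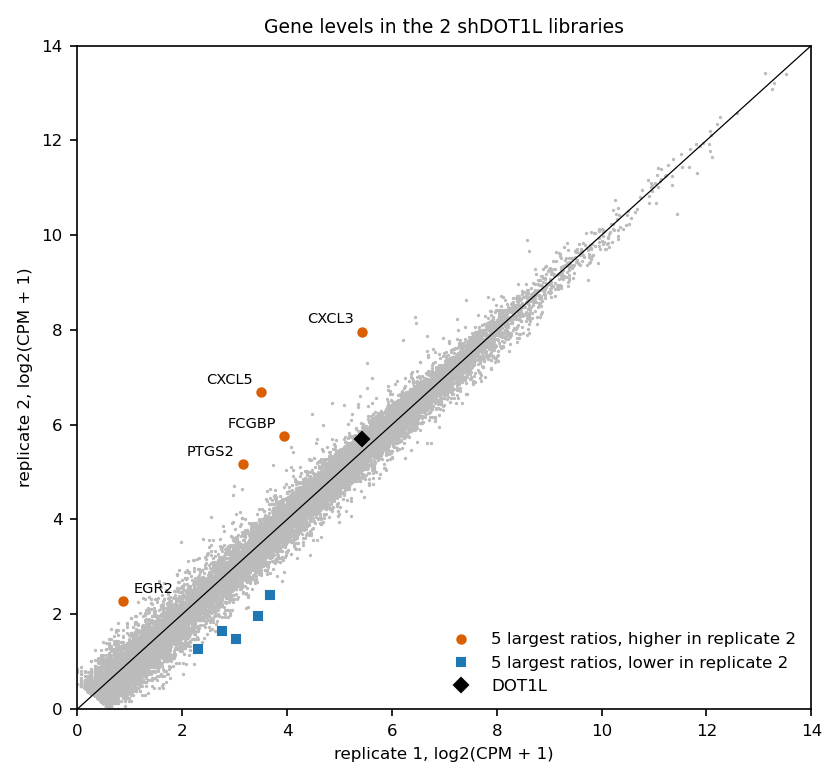
Levels of genes with at least 10 reads over both libraries in replicate 1 (horizontal) against replicate 2 (vertical), as log2(CPM + 1), with the line of equal values; the 5 largest ratios in each direction and DOT1L are marked. CXCL5, CXCL3, EGR2, PTGS2 and FCGBP lie above the line, and Pearson's r over the 13877 detected genes was 0.990.

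Several gene groups moved together between the cultures. Counts of called genes grow with read depth, and the percentiles among random lists were not adjusted for the number of lists. All 11 gastrointestinal markers that differed were higher in replicate 2, of 16 tested, and the count was also 11 when adjusted over the list alone. MUC5AC had a log2 ratio of 1.07, CEACAM6 0.43, TFF1 1.55 and TFF2 0.76. The median log2 ratio of the detected members was 0.43, above all 10000 random lists matched on expression, whose central 95% ran from -0.18 to 0.19. Of 13 mesenchymal genes tested 7 were higher, with CTGF at 1.23, FN1 at 0.89, VIM at 0.38 and TGFBI at 0.33, and 1, SNAI2 at -0.35, was lower; the counts were the same adjusted over the list alone, and the median of 0.36 lay at the 99.98th percentile. Of 27 Wnt genes 15 were higher and 0 lower, also adjusted over the list alone, among them FZD1 at 0.91, LGR4 at 0.77 and CTNNB1 at 0.33, and the median of 0.26 lay at the 99.99th percentile.

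Cell cycle genes were likewise higher in replicate 2, in 16 of 22 tested, with CCNE2 at a log2 ratio of 0.68, CCNE1 at 0.50 and RB1 at 0.21. CCND1 at -0.19 and MKI67 at -0.10 were lower, and adjusted over the list alone 16 were higher and 3 lower. The list median was 0.22, at the 99.93rd percentile. Of 21 glycolysis genes 13 were higher and 0 lower, also adjusted over the list alone, with GAPDH at 0.29 and ALDOA at 0.23, and the median of 0.16 lay at the 98.7th percentile. Interferon response genes went the other way. Of 24 tested 9 were lower, IFI27 at -0.67 and BST2 at -0.23 among them, and 4 were higher, including ISG15 at 0.22; adjusted over the list alone 10 were lower and 5 higher. The median of -0.15 lay at the 0.525th percentile of random lists.

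The remaining lists had medians of detected members within the central 95% of their random lists or too few members to set against them. Of 19 tested DOT1L partners 4 were higher in replicate 2, DOT1L and NPM1 among them, and 4 lower, including KMT2A at -0.15 and MLLT6 at -0.23. Of 24 other lysine methyltransferase genes 6 were higher, including NSD2 at 0.16, KMT2D at 0.17, SETD7 at 0.25 and NSD3 at 0.30, and 1 was lower. Of 11 HOXA genes and cofactors 1 was higher and 0 lower. The median of that list was -0.02 over detected members, but 0.29, at the 98.9th percentile, over members with at least 10 reads in all. Cell cycle inhibitor and damage response genes split into 3 higher and 4 lower of 15, with GADD45A at -0.67 and BAX at -0.14. Stemness genes split into 6 higher and 2 lower of 16, epithelial genes into 9 and 5 of 18, oxidative phosphorylation genes into 12 and 6 of 23, and DNA repair genes into 9 and 1 of 22. The counts of these 8 lists were the same adjusted over the list alone.

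Müllerian markers split into 4 higher and 2 lower of 12, with WFDC2 at -0.56 and LYPD1 at 1.01, and into 5 and 3 adjusted over the list alone. Apoptosis regulators split into 6 and 6 of 18, and into 8 and 6 adjusted over the list alone, and housekeeping genes into 8 and 2 of 14, or 9 and 2. LYZ at 1.15 was the 1 leukocyte marker of 6 tested that differed. Among 4 mesothelial markers CALB2 at -0.39 and LRRN4 at -0.77 were lower, and among 3 endothelial and erythroid markers CDH5 at 1.70 was higher and PECAM1 at -0.41 lower. COL1A1, the 1 fibroblast marker tested, had a log2 ratio of -0.13 with an adjusted p over 0.05. Counts of the 4 lists of other cell types were also the same adjusted over the list alone.

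**Figure D4:**
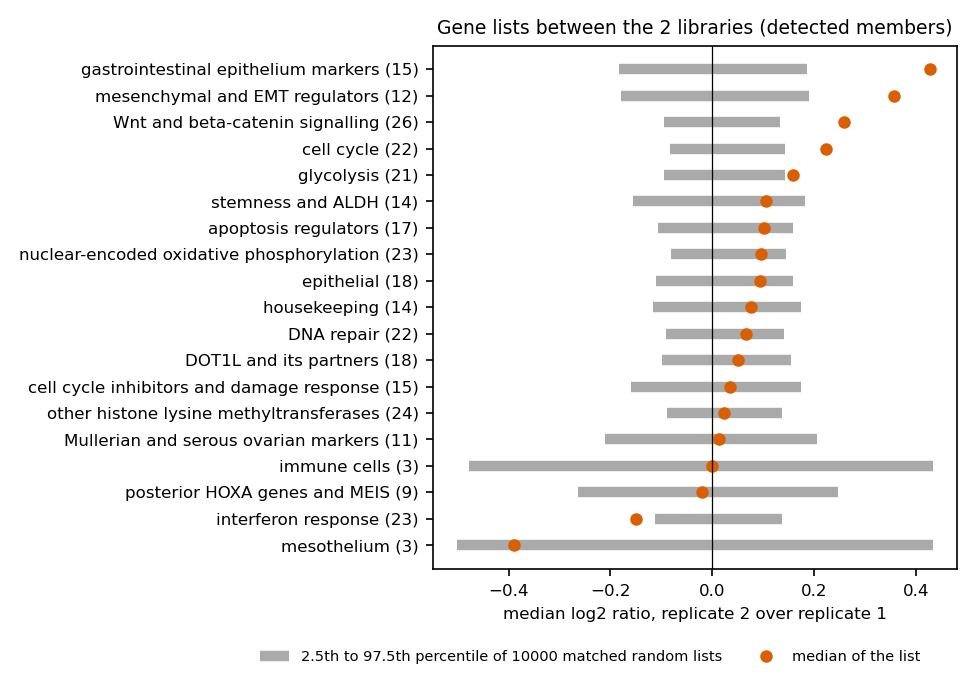
Median log2 ratio of replicate 2 to replicate 1 over the detected members of each list (points, with the number of members in brackets) and the central 95% of 10000 random lists matched on expression (grey bars). Gastrointestinal, mesenchymal, Wnt, cell cycle and glycolysis genes lie above their bars, at 0.43, 0.36, 0.26, 0.22 and 0.16, and interferon response genes below theirs, at -0.15.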

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

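All alternatives were fixed before the data were examined except the scalings of the lists chosen later from the data. The 7 alternatives kept the count of detected genes within 1.5 times, and the 147 recounts of detected list members likewise. All 806 gene levels under other scalings stayed within 1 SD, but those scalings move the 2 libraries in opposite directions. The mean then hardly changes, so that result does not test the levels. Of 1029 recomputed gene ratios 994 kept their call, 14 gained it, 21 lost it and 0 reversed. Another scaling moves a list and its random lists alike, so it says nothing about a list's place among them. With members of at least 10 reads 18 of 19 lists kept their side of the random range, while HOXA genes and cofactors reached a median of 0.29 (98.9th percentile) in place of -0.02, since HOXA7 and HOXA10 then entered. Of 147 list medians 43 moved, 19 of them per kb of exon. The DOT1L percentile was 40.6 per kb of exon and 70.8 among all coding genes with a read, a larger set of mostly lower genes. Pearson's r was 0.98982 and 0.98913 with pseudocounts of 0.5 and 0.1, and 0.99684 with no filter. Requiring a log2 ratio of at least 1 left 447 genes differing. The coefficient of variation was 0.164 by DESeq2, which also overestimated it on simulated counts. Over protein-coding genes alone the mitochondrial share was 6.44% and the share of the top 10 genes 6.19%, since the ribosomal RNA genes of mitochondria leave both. The difference between the lineage lists was 0.02 without replicate 2 and 0.69 without replicate 1, 1.25 per kb of exon, and -5.56 percentage points detected at 2 CPM; the cause was not tested. DESeq2 size factors moved the median of all genes by 0.04 and made 63.0% of differing genes higher in replicate 2, against 54.1% with TMM and 49.1% with total counts. An edgeR or DESeq2 test between the libraries was not run, as 1 library a side leaves no residual degrees of freedom. No paired analysis was possible because there is 1 group. At 0 reads, levels under 0.154 and 0.133 CPM could not be seen.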

Other observations

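The gene groups of this part were picked after the values were seen, as were all tests except those of low expression and unspliced RNA. Chemokine genes were higher in replicate 2, 10 of 13 detected CXCL and CCL genes by the exact binomial test and 0 lower, with a median log2 ratio of 1.40. The neutrophil-attracting genes CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and CXCL8 were all higher, with a median of 1.87, and CXCL8, which encodes interleukin-8, went from 87.0 to 280.3 CPM. CXCL1, CXCL2 and CXCL3 are close homologues that can share reads. Immediate early genes followed, 18 of 20 higher and FOSL1 alone lower at -0.67, with FOSB at 1.65, the phosphatase gene DUSP1 at 1.62 and FOS at 1.24. Mucin and trefoil genes were higher in 8 and lower in 3 of 12, with the gel-forming mucin gene MUC5B at 1.51.

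Genes induced by ATF4, the transcription factor of the amino acid response, were lower in replicate 2, 17 of 23 with 2 higher and a median of -0.41. PHGDH, which starts serine synthesis, was at -1.12, TRIB3 at -1.05, DDIT3 at -1.14 and CHAC1 at -1.07. Cytosolic aminoacyl-tRNA synthetase genes were lower in 13 and higher in 4 of 20, with a median of -0.27 and CARS at -0.57. These groups were picked after the values were seen, all but the synthetase group around genes already at the extremes. The neutrophil-attracting genes are part of the chemokine group. The medians of all these groups thus describe the genes picked and do not test whether the groups moved. Claudin genes had a median of 0.13, S100 genes -0.03 and histone genes 0.04. Genes picked by an integrin symbol had a median of 0.08, but they include ITGB1BP1 and ITGB3BP, which are not integrin genes. LDHB, at 0 reads, lies between GOLT1B with 773 and 906 reads and CMAS with 925 and 966, with KCNJ8 at 0 and ABCC9 at 4 and 3 reads beside it.

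The 33 detected chemokine and immediate early genes had a median log2 ratio of 0.78, with 28 higher and 1 lower. These genes were picked after their ratios were seen, so the size of their median is no test. Random lists matched on exon length and GC content centred on a median of 0.0071, and their central 95% ended at 0.125. Other genes of like length and GC thus hardly moved, which argues against such a bias as the whole cause. A partial share of it was not tested. Leukocytes mixed into replicate 2 stay open: the 16 leukocyte markers summed to 24.8 CPM in replicate 1 and 41.3 CPM in replicate 2, but without LYZ, the most abundant, the other 15 summed to 10.04 and 9.12 CPM, and PTPRC had 0 reads. A difference in the state of the cultures, such as density, serum or handling at harvest, is a hypothesis that may account for it and was not tested, since the labels record none.

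Noncoding genes were lower in replicate 2, though not alone: pseudogenes had a median log2 ratio of -0.11 and ribosomal protein genes -0.09, with 63.2% and 72.2% of them lower. The 916 detected lincRNA, antisense and sense intronic genes had a median log2 ratio of -0.15, with 131 lower and 41 higher, against 0.03 for all coding genes. Coding genes matched on level had a central 95% of medians that began at -0.0385, so low expression does not account for it. Across 12129 coding genes the ratio had a Spearman rho of -0.0259 with gene span over exon length. Reads in introns may not have been counted for coding genes, so this cannot decide on unspliced RNA in replicate 1. Sense intronic genes had a median of -0.167 with 70% lower, and lincRNA genes -0.176 with 67.3% lower. Weaker poly(A) selection in replicate 1 stays open. Histone genes, whose messages typically lack a tail, had a median of 0.0378. That value lay inside the range of noncoding lists of that size, which reached 0.0903. No biological explanation was tested.

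No read fell on the 10 annotated genes from MTAP to CDKN2B on chromosome 9, between 21802543 and 22009363. KLHL9, which ends at 21335380, had 240 and 349 reads, and DMRTA1, which starts at 22446841, had 48 and 76. These flanking genes were picked as the nearest coding genes with reads above a set level in both libraries. That they have reads is thus no test, and any genes between them and the stretch were passed over. At least 90.42% of the exon bases of MTAP, CDKN2A and CDKN2B are free of exons of other genes in GENCODE 29, which argues against reads lost to overlaps, though the authors' annotation is unknown. Loss of this stretch from the genome of the line would leave all 10 genes at 0, as seen, but remains a hypothesis that DNA copy number, not analysed here, would have to decide. Silencing cannot be told apart from loss by RNA counts. Of all stretches of as many consecutive genes, 5.231% were at 0 reads.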
